A study of Homo sapiens with 30 samples.

How the data were processed

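HCT116 and SW480 are human colorectal cancer cell lines grown as cultures. Per the labels, each line was transfected with 10 nM of a control siRNA, of 1 of 2 siRNAs against BRD8 (siBRD8-6, siBRD8-36) or of 1 of 2 siRNAs against TIP60 (siTIP60-2, siTIP60-11), and RNA was taken after 48 h. TIP60 is the protein of the gene listed as KAT5. There were 30 libraries in 10 groups of 3 replicates. The labels do not say whether the replicates of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical. Per the labels' protocols, libraries were made from 100 ng of total RNA with a strand-specific kit and read from 1 end over 60 bases.

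Per the submitters' processing notes, Trimmomatic 0.33, STAR 2.7.3a and RSEM 1.3.3 were used with the hg38 build. The annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited, per the file headers, the expected count of each gene in each library, an estimate that divides reads matching several genes between them and so need not be whole. The authors deposited beside it the TPM of each gene, a value per M counts transcripts corrected for transcript length. Each table listed 60617 genes, and 58444 of the identifiers were found in GENCODE release 29, the annotation used here for gene types, coordinates and 3' UTRs. Of the gene symbols, 34 belonged to several identifiers. Between 9.13% and 13.1% of the genes of a library had an expected count that was not whole. Histone and ribosomal protein genes share sequence with close copies and pseudogenes, so their values are less certain than those of single-copy genes, and so are those of genes that overlap another gene.

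Expected counts were rounded to whole numbers and summed to between 13.4 and 18.6 M counts per library in HCT116 (median 16.7) and between 7.07 and 11.7 M counts in SW480 (median 8.92), with the SW480 control libraries at 7.07 to 7.69 M counts. No 2 replicates held identical values or agreed within sampling noise: the chi-square per gene of the 30 replicate pairs, over genes with at least 20 counts in both replicates together, lay between 1.47 and 21.3. All 30 libraries were therefore counted as separate samples.

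Each line was fitted on its own with all 15 libraries, using the quasi-likelihood test of edgeR 4.0.16 (robust, TMM scaling, genes kept by its expression filter) in R 4.3.3. A gene was called for a target where both siRNAs moved it in one direction and the larger of the 2 p-values stayed under 0.05 after Benjamini-Hochberg adjustment. BRD8 and TIP60 depletion were compared through the mean of the 2 siRNAs of each target. A four-way call asked in addition that each BRD8 siRNA differ from each TIP60 siRNA in one direction; it was added after the data were seen. The lines were compared through the interaction term of a fit of all 30 libraries, and the siRNAs of a target through their direct difference. Standard errors are the size of the log2 fold change divided by the square root of F. CPM values are computed from the rounded counts with TMM scaling. A fold against a group at 0 was to be computed against a floor of 3 counts over the group. No such fold of a single gene is printed, nor any fitted fold as a bound. List medians between lines are given also with group counts set to that floor.

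The 21 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The lists were the pre-replication complex, the replication fork, other G1/S genes, G2/M genes, subunits of the TIP60 complex, homologous recombination and Fanconi anaemia repair genes, replication-dependent histones, interferon-stimulated genes, NF-kappaB genes, WNT targets, ribosome biogenesis, ribosomal proteins, cholesterol synthesis, stress genes of ATF4 and the endoplasmic reticulum, hypoxia and glycolysis, epithelial genes, mesenchymal genes, mitochondrially encoded mRNAs, and fibroblast and leukocyte markers as other cell types. The remaining list and a few genes are not reported here, but the list is included in the numbers of lists called. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. The rule for named genes took BRD8 and KAT5, and for each target and line the 10 protein-coding genes that rose and the 10 that fell most by the smaller of the 2 changes, with a mean count of at least 50. It also took up to 4 members of each list with the largest change, 5 genes in each direction for differences between targets and lines, and 3 for differences between siRNAs. The genes described were drawn mostly from those whose call held in every alternative, a choice made after the values were seen. RIGI was matched under its older symbol DDX58.

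The alternatives were DESeq2 1.42.0 and its size factors, no filter, a stricter filter (CPM of at least 1 in 3 libraries), limma on log2(TPM + 1), the replicate number as a block, fits of the compared groups alone, a minimum log2 fold change of 1, the mean of the 2 siRNAs, each siRNA alone, a mean count of at least 50 for correlations, and leaving out each library. An adjustment for the trend of each library with gene length, four-way calls and calls by both siRNAs between lines were added after the data were seen, as were tests of the lists between lines with members tested in both lines, with the floor and without single libraries. To look for seed matches, the 7-mers of 3' UTRs (15686 tested, 10044 of 10648 genes with a 3' UTR) were ranked by the change of genes holding them. Random splits numbered 100 within a line and 40 between lines. Shared controls were addressed by simulating unchanged groups against the same control libraries 20 times. With 3 control libraries per line, no split leaves 2 in each part.

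The tests were tested on simulated data with the real means and library sizes. For both BRD8 siRNAs in HCT116 (15626 genes), 16% of planted genes were recovered at a fold of 1.25, 60% at 1.5, 84% at 2 and 84% at 4, with 0 false calls. In SW480 (14980 genes) the shares were 12%, 52%, 82% and 86%, with 0 false calls. For the BRD8 difference between lines (16600 genes) they were 14%, 42%, 70% and 78%, with 5 false calls.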

Results

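RNA was sequenced from HCT116 and SW480 cells, human colorectal cancer lines, after depletion of BRD8, a bromodomain subunit of the TIP60 acetyltransferase complex, or of TIP60 itself, its catalytic subunit encoded by KAT5. Each line had a control siRNA, 2 siRNAs against BRD8 and 2 against TIP60, with 3 libraries per group, 30 libraries in all. Total expected counts per library lay between 13.4 and 18.6 M counts in HCT116 and between 7.07 and 11.7 M counts in SW480, where the control libraries were the shallowest (7.07 to 7.69 M counts). Unless stated otherwise, changes are the mean log2 fold change of the 2 siRNAs of a target against control ± SE, with n = 3 libraries per group, and expression levels are CPM ± SD. Genes described as risen or fallen passed the test with both siRNAs in one direction. List members counted neither as risen nor as fallen were not called, and counts adjusted over the list alone are given where they differ from those over all genes tested.

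The siRNAs lowered their targets in both lines. BRD8 (ENSG00000112983, chromosome 5, 138139766 to 138178986 on the minus strand of GRCh38, a protein-coding gene) stood at 41.9 ± 3.39 CPM in HCT116 control cells. It stood at 8.73 ± 0.505 with siBRD8-6 (20.8% of control, log2 fold change −2.27, SE 0.0889, adjusted p = 4.42e-13) and at 5.95 ± 0.507 with siBRD8-36 (14.2%, −2.82, SE 0.0943, adjusted p = 1.68e-14). In SW480 it went from 54.7 ± 4.07 to 13.4 ± 1.00 (24.5%, adjusted p = 5.12e-16) and 11.6 ± 0.623 (21.2%, adjusted p = 4.90e-17). KAT5 (ENSG00000172977, chromosome 11, 65711996 to 65719604 on the plus strand, protein-coding) went from 48.5 ± 1.85 in HCT116 control cells to 3.57 ± 0.0379 with siTIP60-2 (7.36%, adjusted p = 6.09e-17) and 4.80 ± 0.159 with siTIP60-11 (9.91%, adjusted p = 3.28e-16). In SW480 it went from 39.5 ± 1.85 to 3.16 ± 0.765 (8.0%, adjusted p = 2.96e-18) and 5.39 ± 0.290 (13.6%, adjusted p = 1.81e-17). With siBRD8-36, KAT5 was also lower, at 39.0 ± 1.60 in HCT116 (80.5%, adjusted p = 8.03e-05) and 29.7 ± 0.915 in SW480 (75%, adjusted p = 0.000206). With siBRD8-6 it stood at 53.5 ± 1.99 in HCT116 (110%, adjusted p = 0.0373) and 41.5 ± 1.87 in SW480 (adjusted p = 0.490). BRD8 itself passed the test with neither TIP60 siRNA, at 43.5 ± 3.21 (adjusted p = 0.600) and 42.7 ± 2.76 (0.800) in HCT116 and at 60.9 ± 5.86 (0.101) and 51.4 ± 2.47 (0.368) in SW480.

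**Figure D1:**
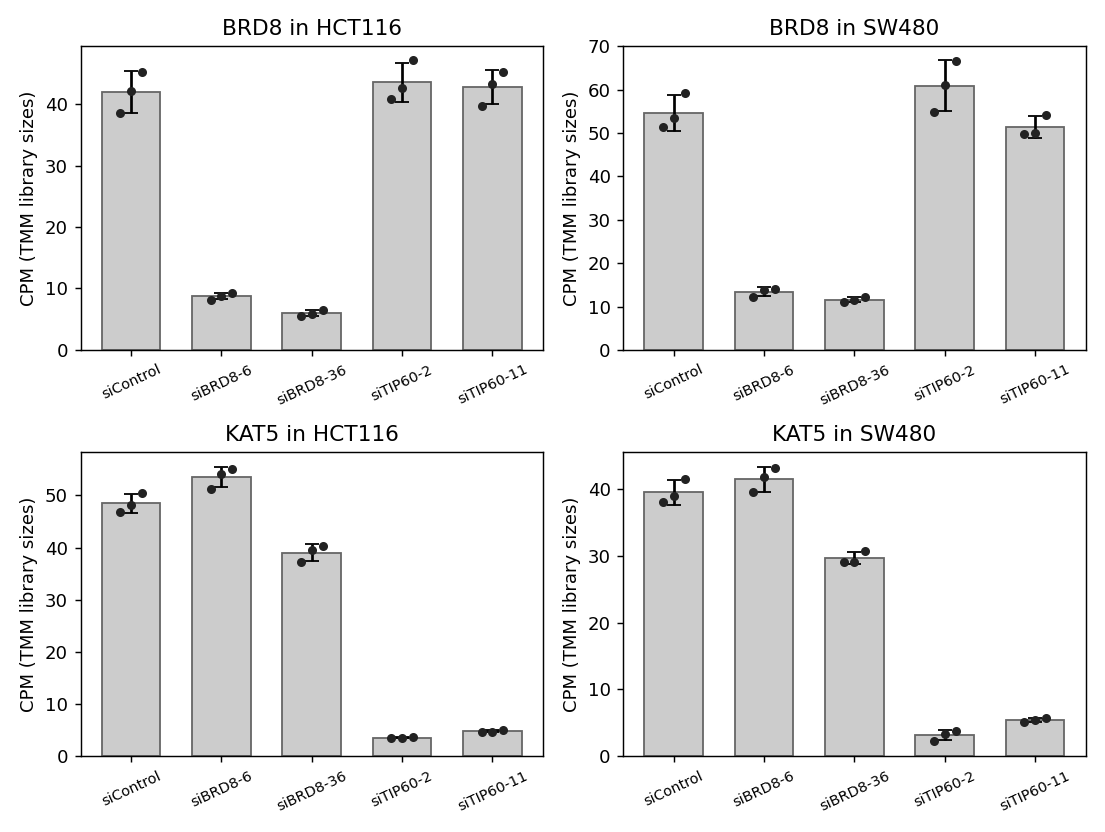
Expression of BRD8 and KAT5 in CPM for each siRNA in HCT116 and SW480. Bars are means of 3 libraries, error bars SD and points single libraries. BRD8 fell to between 14.2% and 24.5% of control with its own siRNAs and KAT5 to between 7.36% and 13.6%.

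The effect of BRD8 depletion on gene expression was asked first for HCT116 cells. Genes of DNA replication and mitosis were lower and some core histone genes were higher, and cholesterol synthesis genes were higher mainly with siBRD8-36. PLK2, a polo-like kinase, rose from 79.5 ± 3.45 to 293 ± 8.03 with siBRD8-6 and 345 ± 22 with siBRD8-36 (2.00 ± 0.0494, adjusted p = 5.43e-14). MCM4, a subunit of the replicative helicase, fell from 223 ± 7.12 to 81.4 ± 7.14 and 83.1 ± 1.87 (−1.44 ± 0.0505, adjusted p = 8.23e-12). ASNS, the asparagine synthetase induced by ATF4, fell from 828 ± 25.2 to 239 ± 18.4 and 149 ± 6.59 (−2.13 ± 0.0919, adjusted p = 2.90e-08). In all, 3891 of 15919 genes were called, 1943 higher and 1948 lower, 358 of them at least 2-fold with both siRNAs. For 3696 of the 3891 all 6 depleted libraries lay beyond all 3 control libraries, where chance gives 2.38% of genes and 29.3% of the genes tested did so. With limma on log2(TPM + 1), 2375 genes were called. By 3' UTR sites of the 7-mers found for the BRD8 siRNAs, counted by 6 bases and not matched for UTR length, of 5141 genes without a site of either siRNA 827 were higher and 544 lower (10.6%), and of 3537 with sites of both 412 were higher and 656 lower (18.5%).

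Among single genes in HCT116, the largest rises by the smaller of both changes with BRD8 siRNAs included the histone genes H2BC5 (2.69 ± 0.104), H2AC6 (2.43 ± 0.106) and H2BC12 (2.32 ± 0.105), whose reads may be shared with close copies. GALNT5 (2.39 ± 0.0951), CGN, which encodes the tight junction protein cingulin (1.83 ± 0.0562), and the DNA-binding factor ARID3A (1.91 ± 0.0756) rose as well. NIBAN1 (−2.78 ± 0.0928), the LIM protein gene FHL1 (−2.42 ± 0.0899), PCK2, a mitochondrial phosphoenolpyruvate carboxykinase (−2.57 ± 0.149), and CDKN3, a phosphatase acting on cyclin-dependent kinases (−1.95 ± 0.0804), fell.

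Of the 14 members of the pre-replication complex, which licenses origins, 11 fell after BRD8 depletion in HCT116 (median −1.04, camera adjusted p = 8.64e-10, and 0.00342 with an estimated correlation). The list's median was −0.43 with siBRD8-6 and −1.40 with siBRD8-36, and MCM2 fell by 0.50 with the former and fell by 3.37 with the latter (from 212 ± 9.07 to 150 ± 4.72 and 20.5 ± 0.868 CPM). At the replication fork, 20 of 37 genes fell (21 adjusted over the list alone, median −0.70, adjusted p = 4.45e-15, and 0.00141 with an estimated correlation), among them CDC45 (−1.38 ± 0.0659), GINS2 (−1.23 ± 0.0505) and the primase gene PRIM1 (−1.18 ± 0.0610). Other G1/S genes fell in 20 of 34 cases (22 adjusted over the list alone, median −0.71, adjusted p = 1.42e-14, estimated 0.00804), with MSH6 of mismatch repair at −1.19 ± 0.0602. G2/M genes fell in 22 of 35 cases (23 adjusted over the list alone, median −0.88, adjusted p = 1.69e-19, estimated 0.0154), with the spindle midzone protein gene PRC1 at −1.70 ± 0.0466 and CDK1 at −1.48 ± 0.0486. Of 27 repair genes of homologous recombination and the Fanconi pathway, 17 fell (18 lower and 1 higher adjusted over the list alone, median −0.87, adjusted p = 8.77e-10, estimated 0.0478), with XRCC2 at −1.69 ± 0.0958 and BRIP1 at −1.26 ± 0.0797. With siBRD8-6 and siBRD8-36, medians were −0.26 and −1.10 at the fork, −0.24 and −1.20 for G1/S, −0.28 and −1.60 for G2/M and −0.37 and −1.38 for repair. With siBRD8-6 alone and an estimated correlation, the pre-replication and fork lists held (adjusted p = 0.0186 for each). The G1/S (0.317), G2/M (0.320) and repair (0.317) lists did not, so that their calls with an estimated correlation rested on siBRD8-36.

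The antiproliferative gene BTG2 (1.53 ± 0.0445) and the cyclin-dependent kinase inhibitor gene CDKN1A (1.21 ± 0.0641) rose. Replication-dependent histone genes rose in 6 of 8 cases (7 adjusted over the list alone, median 1.66, adjusted p = 2.72e-05, and 0.00517 with an estimated correlation). Cholesterol synthesis genes rose in 10 of 24 (median 0.48, adjusted p = 3.37e-08, estimated 0.00342), with HMGCS1 at 1.24 ± 0.0529 and NSDHL at 0.85 ± 0.0644. The cholesterol list's median was 0.11 with siBRD8-6, which by itself gave no call (adjusted p = 0.124), and 0.89 with siBRD8-36 (6.48e-10). Ribosome biogenesis genes rose in 16 of 29 (18 adjusted over the list alone, median 0.25, adjusted p = 2.96e-07, estimated 0.00342), with UTP20 at 0.67 ± 0.0740. Mesenchymal genes rose in 5 of 16 and fell in 1 (6 and 1 adjusted over the list alone, median 0.56, adjusted p = 0.00108, estimated 0.0145), with FN1 at 0.67 ± 0.0883 and SPARC at −2.31 ± 0.326. With an estimated correlation siBRD8-6 alone called neither the mesenchymal list (adjusted p = 0.129) nor the cholesterol list (0.320). The stress list of ATF4 and the endoplasmic reticulum held 16 of 25 genes that fell (median −1.04, adjusted p = 2.71e-11 but 0.0674 with an estimated correlation), with DDIT4, an mTORC1 inhibitor, at −2.35 ± 0.0809 and the cystine transporter gene SLC7A11 at −2.16 ± 0.0932. Mitochondrially encoded mRNAs rose in 3 of 13 cases (median 0.46, adjusted p = 0.00502 but 0.430 with an estimated correlation), with MT-ATP8 at 0.51 ± 0.0864. The mitochondrial share of counts was 1.61 ± 0.0516% in control and 2.01 ± 0.333% and 2.30 ± 0.390% in depleted libraries.

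WNT targets rose in 7 of 18 cases and fell in 1 (8 and 1 adjusted over the list alone, median 0.32, adjusted p = 0.0430 but 0.174 with an estimated correlation), with BMP4 at 1.42 ± 0.0452 and AXIN2 at 1.32 ± 0.0791. With TPM the WNT median was 0.19 and that of mesenchymal genes 0.34. The WNT list's median was 0.12 with siBRD8-6 (adjusted p = 0.604) and 0.57 with siBRD8-36 (0.00176). Its call ended without siBRD8-36 replicate 1 (adjusted p = 0.0526), without control replicate 2 (0.0923) and after adjustment for gene length (0.0780). Not called in HCT116 after BRD8 depletion were the TIP60 complex subunits (4 of 16 higher, 2 lower, 4 and 4 adjusted over the list alone, median −0.02 with camera's direction upward, adjusted p = 0.712, MORF4L2 0.44 ± 0.0383, YEATS4 −0.77 ± 0.0839). Interferon-stimulated genes were not called either (6 of 32 higher, 3 lower, 7 and 3 adjusted over the list alone, median 0.12, adjusted p = 0.126, OASL 1.35 ± 0.134, OAS3 −1.17 ± 0.0734). NF-kappaB genes had 1 of 14 higher and 3 lower (median −0.11, adjusted p = 0.290, ICAM1 −0.85 ± 0.0913). Hypoxia and glycolysis genes had 3 of 23 higher and 3 lower (median 0.08, adjusted p = 0.404, SLC2A1 0.83 ± 0.0444), and epithelial genes 7 of 17 higher and 3 lower (7 and 4 adjusted over the list alone, median 0.20, adjusted p = 0.181, but 0.0481 with siBRD8-36 alone, KRT19 0.92 ± 0.0622, CLDN3 −1.60 ± 0.116). Ribosomal protein genes fell in 2 of 50 cases (1 adjusted over the list alone, median −0.10, adjusted p = 0.270, RPL15 −0.39 ± 0.0598). Their share of counts was 8.92% in control replicate 2 and 6.79% and 6.50% in the other control libraries, and the list was called lower without control replicate 1 (adjusted p = 0.0215) or 3 (0.0137). Of markers of other cell types, the 2 fibroblast genes had a median of 0.73 (COL1A1 1.15 ± 0.0842, 1 of 2 called) and the 4 leukocyte genes, 1 of them higher, a median of 0.81 (adjusted p = 0.532).

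TIP60 depletion in HCT116 raised KRT13 and MYC and lowered DDIT3 and ASNS. KRT13, a keratin of stratified epithelia, rose from 0.715 ± 0.232 to 21.1 ± 1.91 with siTIP60-2 and 35.6 ± 2.33 with siTIP60-11 (5.21 ± 0.184, adjusted p = 2.89e-12). MYC, a growth-promoting transcription factor counted among the WNT targets, rose from 383 ± 18.4 CPM by 1.80 ± 0.0568 (adjusted p = 2.65e-13). DDIT3, the stress factor CHOP, fell from 75 ± 6.45 to 26.5 ± 3.27 and 10.8 ± 0.475 (−2.14 ± 0.0788, adjusted p = 4.10e-10). In all, 4436 of 15919 genes were called, 2184 higher and 2252 lower, 435 of them at least 2-fold, and for 4276 all 6 depleted libraries lay beyond all 3 control libraries (33.5% of the genes tested did so). With limma on log2(TPM + 1), 2764 genes were called.

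Further genes with large rises after TIP60 depletion in HCT116 were the carboxypeptidase gene CPA4 (3.64 ± 0.0768), the matrix metalloprotease gene MMP7 (3.38 ± 0.191), COL17A1, a collagen of hemidesmosomes (2.89 ± 0.161), KRT80 (2.81 ± 0.122) and the integrin gene ITGB8 (2.31 ± 0.111). The ubiquitin ligase gene NEDD4 (−2.70 ± 0.0763), NIBAN1 (−2.59 ± 0.0923), ASNS (−2.47 ± 0.0924) and the neutral amino acid transporter gene SLC1A4 (−2.31 ± 0.115) fell.

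No direction was called for the replication lists after TIP60 depletion in HCT116. Among pre-replication genes 1 of 14 rose and 1 fell (median about −0.00, mean 0.02, the sign depending on the scaling, camera adjusted p = 0.798). At the fork 2 of 37 rose and 6 fell (median −0.02, upward after length adjustment, adjusted p = 0.760). Of other G1/S genes, 7 of 34 rose and 6 fell (8 and 6 adjusted over the list alone, median about −0.00, adjusted p = 0.992), with E2F1 at 0.72 ± 0.0799 and E2F8 at −0.60 ± 0.0817. Repair genes had 3 of 27 higher and 1 lower (median 0.02, downward with TPM, adjusted p = 0.751). G2/M genes fell in 17 of 35 cases and rose in 1 (median −0.26, adjusted p = 3.41e-05 but 0.313 with an estimated correlation), with the mitotic kinase gene NEK2 at −1.02 ± 0.0539 and CENPA, the centromeric histone, at −0.64 ± 0.0764.

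With TIP60 siRNAs in HCT116, PLK2 (2.12 ± 0.0497) and CDKN1A (1.41 ± 0.0647) rose. Ribosome biogenesis genes rose in 12 of 29 (median 0.25, adjusted p = 1.93e-06, and 0.0148 with an estimated correlation), with UTP20 at 1.2 ± 0.0741 and NOLC1 at 0.81 ± 0.0442. Of the lists called here, the following were lost with an estimated correlation. Cholesterol genes rose in 7 of 24 (8 adjusted over the list alone, median 0.35, adjusted p = 0.000103, estimated 0.0510), with NSDHL at 0.67 ± 0.0647. Their median was 0.47 with siTIP60-2 and 0.05 with siTIP60-11 (adjusted p = 0.505). Histone genes rose in 2 of 8 (median 0.87, adjusted p = 0.00942, estimated 0.0781), H2BC5 by 2.13 ± 0.106. The histone median was 0.50 with siTIP60-2 (adjusted p = 0.0713) and 1.28 with siTIP60-11, and that of the mean 0.50 with TPM. Epithelial genes rose in 8 of 17 and fell in 2 (median 0.32, adjusted p = 0.0190, estimated 0.0996), with ELF3 at 1.62 ± 0.0604 and the splicing regulator ESRP1 at −1.18 ± 0.0508. WNT targets rose in 6 of 18 and fell in 1 (6 and 2 adjusted over the list alone, median 0.20, adjusted p = 0.0213, estimated 0.188, and 0.0570 without control replicate 2), with BMP4 at 2.29 ± 0.0468. The WNT median was 0.41 with siTIP60-2 and −0.13 with siTIP60-11 (camera's direction upward, adjusted p = 0.572). Stress genes fell in 20 of 25 and rose in 1 (median −0.71, adjusted p = 3.56e-12, estimated 0.0996), with PHGDH of serine synthesis at −2.28 ± 0.0880. Mitochondrial mRNAs rose in 11 of 13 (12 adjusted over the list alone, median 0.83, adjusted p = 2.44e-05, estimated 0.313), MT-CYB by 0.99 ± 0.190. The mitochondrial share of counts was 2.35 ± 0.195% and 2.94 ± 0.185% against 1.61 ± 0.0516% in control.

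Among lists without a call, the TIP60 complex had 4 of 16 subunits higher and 3 lower (median 0.10, adjusted p = 0.760, EPC1 0.92 ± 0.0779, MEAF6 −0.85 ± 0.0600). Interferon-stimulated genes had 7 of 32 higher and 2 lower (median 0.10, adjusted p = 0.329, ISG20 −1.52 ± 0.139) and NF-kappaB genes had 2 of 14 higher and 3 lower (median 0.30, adjusted p = 0.751, BIRC3 1.95 ± 0.0961). Hypoxia genes had 3 of 23 higher and 5 lower (median −0.05, upward with TPM, adjusted p = 0.760, VEGFA −1.37 ± 0.0545). Mesenchymal genes had 2 of 16 higher and 4 lower (3 and 5 adjusted over the list alone, median about −0.00, mean 0.03, camera's direction downward, adjusted p = 0.789, TPM1 −1.63 ± 0.0651). The 50 ribosomal protein genes had a median of −0.05, upward after length adjustment (adjusted p = 0.875, RPL12 0.20 ± 0.0536, adjusted p = 0.0655). The list was called higher (adjusted p = 0.000779) without control replicate 2, the library with the share of 8.92%. The 2 fibroblast genes had a median of 0.25 and the 4 leukocyte genes, 2 of them higher, a median of 1.24 (adjusted p = 0.194, LYZ 2.64 ± 0.316).

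In SW480, BRD8 depletion was likewise followed by lower expression of replication and mitosis genes, and WNT targets were higher and stress genes lower. APCDD1, an inhibitor of WNT signalling, rose from 177 ± 1.07 to 863 ± 24.9 with siBRD8-6 and 551 ± 28.2 with siBRD8-36 (1.96 ± 0.0504, adjusted p = 5.69e-18). The transcription factor gene PROX1 rose from 13.9 ± 0.790 to 57.6 ± 1.19 and 89.4 ± 12 (2.37 ± 0.0915, adjusted p = 1.40e-14). CDC6, which loads the replicative helicase, fell from 108 ± 6.29 to 53.7 ± 3.16 and 19.4 ± 0.315 (−1.75 ± 0.0587, adjusted p = 3.23e-12). The stress factor gene ATF3 fell from 70.0 ± 4.31 to 14.9 ± 1.93 and 18.8 ± 1.00 (−2.06 ± 0.0695, adjusted p = 1.42e-15). In all, 4110 of 15277 genes were called, 1970 higher and 2140 lower (47.9% higher), 436 of them at least 2-fold, and for 4001 all 6 depleted libraries lay beyond all 3 control libraries (35.2% of the genes tested did so). With limma on log2(TPM + 1) the split was 3144 higher and 548 lower (85.2% higher), that scaling shifted the median of all genes by 0.227, and by 0.180 for TIP60 depletion.

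Other genes with large rises after BRD8 depletion in SW480 were the transcription factor genes TSHZ2 (2.49 ± 0.131) and EHF (1.83 ± 0.131), PLEKHB1 (2.38 ± 0.122) and CEMIP, which takes part in hyaluronan breakdown (1.90 ± 0.121). HKDC1, a hexokinase-like gene (−2.38 ± 0.111), NT5E, the ectoenzyme CD73 (−2.31 ± 0.0769), CDKN3 (−1.95 ± 0.0780) and the kinetochore gene CENPK (−1.81 ± 0.110) fell.

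Of the 14 pre-replication genes, 9 fell in SW480 (10 adjusted over the list alone, median −0.73, at −0.41 with siBRD8-6 and −0.95 with siBRD8-36, camera adjusted p = 1.91e-08, and 0.00976 with an estimated correlation). ORC6 fell (−1.53 ± 0.104), and MCM4 went from 149 ± 6.06 to 74.3 ± 6.33 and 97.8 ± 5.04. Fork genes fell in 24 of 37 cases (28 adjusted over the list alone, median −0.72, adjusted p = 1.35e-11, estimated 0.00953), with CDC45 at −1.50 ± 0.111 and RFC4 at −1.32 ± 0.0577. Other G1/S genes fell in 17 of 34 and rose in 1 (17 and 2 adjusted over the list alone, median −0.57, adjusted p = 2.17e-09, estimated 0.0249), with the thymidylate synthase gene TYMS at −1.33 ± 0.0662. G2/M genes fell in 30 of 35 (31 adjusted over the list alone, median −1.12, adjusted p = 3.18e-23, estimated 0.00478), with CDK1 at −1.90 ± 0.0756 and the mitotic kinase gene AURKA at −1.39 ± 0.0494. Repair genes fell in 19 of 27 and rose in 1 (20 and 1 adjusted over the list alone, median −0.73, adjusted p = 1.91e-08, estimated 0.00894). With siBRD8-6 and siBRD8-36, medians were −0.42 and −0.87 at the fork, −0.33 and −0.84 for G1/S, −0.71 and −1.51 for G2/M and −0.49 and −0.92 for repair. With TPM, which shifted all genes, medians were smaller, at −0.38 for pre-replication, −0.35 for fork, −0.25 for G1/S and −0.23 for repair genes. Less the median of all genes they were −0.61, −0.57, −0.48 and −0.46. With siBRD8-6 alone and an estimated correlation, G2/M (adjusted p = 0.0311) and repair genes (0.0419) held, and pre-replication (0.0538), fork (0.0514) and G1/S genes (0.262) did not.

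WNT targets rose in 15 of 23 cases after BRD8 depletion in SW480 (median 0.83, adjusted p = 1.50e-09, and 0.00953 with an estimated correlation), with SOX4 at 1.94 ± 0.0835 and NOTUM, a secreted WNT inhibitor, at 1.44 ± 0.0690. Stress genes fell in 17 of 26 (median −0.64, adjusted p = 2.27e-12, estimated 0.00953), with DDIT3 at −1.55 ± 0.0513. With an estimated correlation siBRD8-6 alone called the WNT (adjusted p = 0.0311) but not the stress list (0.0865). With TPM the stress median was −0.38, or −0.61 less that of all genes, and the ribosomal protein median below was −0.03, or −0.25. Interferon-stimulated genes rose in 4 of 32 and fell in 1 (2 and 1 adjusted over the list alone, median 0.29, adjusted p = 0.0237, estimated 0.0496), with OAS1 at 1.81 ± 0.176. With siBRD8-6 alone that list gave no call (median 0.20, adjusted p = 0.109). Histone genes fell in 12 of 25 and rose in 2 (13 and 2 adjusted over the list alone, median −0.99, adjusted p = 0.0251 but 0.340 with an estimated correlation, and 0.0959 after length adjustment), with H1-4 at −2.79 ± 0.422. The histone median was −0.70 with siBRD8-6 (adjusted p = 0.249) and −1.51 with siBRD8-36. Ribosomal protein genes fell in 37 of 50 cases (42 adjusted over the list alone, median −0.31, adjusted p = 2.57e-10 but 0.351 with an estimated correlation), RPS13 at −0.68 ± 0.0629 and RPS6 at −0.64 ± 0.0681. The control libraries of SW480 stood apart in the same respect: ribosomal protein genes took 9.76 ± 0.221% of their counts against 7.84% to 8.45% in the other groups. Their mean gene length was 2110 ± 14.4 bases against 2199 to 2320, and the small RNAs 7SK and 7SL took 0.289 ± 0.0255% against 0.0952% to 0.166%. With the trend of each library with gene length taken out, the median of the ribosomal protein list was −0.07 (2 higher, 16 lower, adjusted p = 0.00991).

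Without a call after BRD8 depletion in SW480 were TIP60 complex subunits (2 of 16 higher, 2 lower, median −0.08, but 0.18 with TPM, adjusted p = 0.520, YEATS4 −1.16 ± 0.0733) and NF-kappaB genes (1 of 11 lower, median 0.28, adjusted p = 0.202). Ribosome biogenesis genes had 5 of 29 higher and 4 lower (5 and 5 adjusted over the list alone, median −0.04, upward with TPM or length adjustment, mean 0.02, adjusted p = 0.963, UTP20 0.62 ± 0.0686). That list was called lower with siBRD8-6 alone (median −0.24, adjusted p = 0.0261) and stood at 0.19 with siBRD8-36 (0.0527). Cholesterol genes had 4 of 24 higher and 5 lower (median 0.12, adjusted p = 0.650, FDPS −0.52 ± 0.0484) and hypoxia genes 5 of 22 higher and 3 lower (median −0.15, but 0.08 with TPM, adjusted p = 0.202, NDRG1 −0.87 ± 0.0505). Epithelial genes had 7 of 16 higher and 3 lower (7 and 4 adjusted over the list alone, median 0.16, adjusted p = 0.158, CDX2 1.22 ± 0.0826). Mesenchymal genes had 3 of 16 higher and 2 lower (median 0.38, adjusted p = 0.0829, SNAI2 −1.89 ± 0.101, FN1 0.99 ± 0.0576). Mitochondrial mRNAs had 3 of 13 lower (median −0.12, upward with TPM or length adjustment, adjusted p = 0.158, and 0.0394 without siBRD8-6 replicate 2). They were called lower with siBRD8-36 alone (−0.22, adjusted p = 0.0138, estimated 0.417). The 2 fibroblast genes had a median of 0.47. The 4 leukocyte genes, with CORO1A at 1.14 ± 0.129, had a median of 1.17 (adjusted p = 0.0525), and 2.30 with siBRD8-36 alone (adjusted p = 0.00677). Their call was reached without control replicate 2 (0.0471) or 3 (0.0388), without siTIP60-11 replicate 1 (0.0428), 2 (0.0499) or 3 (0.0489), without siTIP60-2 replicate 1 (0.0494), 2 (0.0389) or 3 (0.0495), and after length adjustment (0.0400).

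TIP60 depletion in SW480 raised WNT targets and lowered genes of the stress response and of the endoplasmic reticulum. GZMB, which encodes the protease granzyme B, rose from 4.03 ± 0.412 to 34.1 ± 6.64 with siTIP60-2 and 22.8 ± 2.29 with siTIP60-11 (2.79 ± 0.167, adjusted p = 1.53e-10). ABAT, a transaminase that breaks down GABA, rose from 21.9 ± 1.45 to 98.0 ± 2.35 and 125 ± 4.40 (2.34 ± 0.0712, adjusted p = 4.77e-17). RBBP4, a histone-binding subunit of several chromatin complexes, fell from 210 ± 3.44 to 74.1 ± 7.59 and 79.5 ± 8.61 (−1.45 ± 0.0605, adjusted p = 1.03e-13). DDIT3 fell from 383 ± 1.19 to 192 ± 4.26 and 134 ± 1.56 (−1.26 ± 0.0512, adjusted p = 1.57e-12). In all, 3606 of 15277 genes were called, 1754 higher and 1852 lower (48.6% higher), 285 of them at least 2-fold, and for 3547 all 6 depleted libraries lay beyond all 3 control libraries (34.4% of the genes tested did so). With limma on log2(TPM + 1) the split was 2171 higher and 461 lower (82.5% higher).

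Other genes with large changes after TIP60 depletion in SW480 were the nuclear receptor gene NR2F1 (2.25 ± 0.120), SYTL2 (2.50 ± 0.10) and KRT74 (2.32 ± 0.114), which rose. INHBE, an inhibin subunit (−1.85 ± 0.0811), NUCB2 (−1.68 ± 0.0592), SPCS3 of the signal peptidase (−1.54 ± 0.0625) and CCPG1, a receptor for turnover of the endoplasmic reticulum (−1.41 ± 0.0643), fell.

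WNT targets rose in 14 of 23 cases with TIP60 siRNAs in SW480 and fell in 1 (16 and 1 adjusted over the list alone, median 0.60, adjusted p = 2.76e-09, and 0.0233 with an estimated correlation). PROX1 rose by 1.3 ± 0.0974, APCDD1 by 1.00 ± 0.0486 and RNF43, a ligase that removes WNT receptors, by 0.98 ± 0.0705. Stress genes fell in 19 of 26 and rose in 1 (20 and 1 adjusted over the list alone, median −0.53, adjusted p = 3.70e-12, estimated 0.0233), with the chaperone gene HSPA5 at −1.16 ± 0.0397 and XBP1 at −1.09 ± 0.0480. With siTIP60-2 alone neither list passed with an estimated correlation (adjusted p = 0.0501 for each). With TPM the stress median was −0.31, that of ribosomal proteins −0.09 and that of mitochondrial mRNAs 0.55, or −0.49, −0.27 and 0.37 less the median of all genes. The remaining calls were lost with an estimated correlation. Ribosomal protein genes fell in 24 of 50 (30 adjusted over the list alone, median −0.30, adjusted p = 6.90e-10, estimated 0.448, RPS6 −0.47 ± 0.0684). The control libraries stood apart by their ribosomal protein share of 9.76 ± 0.221%. After length adjustment the median was −0.12 (1 higher, 19 lower, adjusted p = 0.000521). Mitochondrial mRNAs rose in 1 of 13 (median 0.34, adjusted p = 7.36e-06, estimated 0.322, MT-ND5 0.58 ± 0.0535), and in 10 of 13 after length adjustment. The list's median was 0.03 with siTIP60-2 (adjusted p = 0.863) and 0.69 with siTIP60-11 (3.98e-10). The mitochondrial share of counts was 2.74 ± 0.0570% in control, 2.86 ± 0.0529% with siTIP60-2 and 4.17 ± 0.146% with siTIP60-11. Hypoxia genes fell in 8 of 22 and rose in 1 (median −0.20, but 0.03 with TPM, adjusted p = 0.0160, estimated 0.235, VEGFA −1.03 ± 0.0686). Ribosome biogenesis genes fell in 7 of 29 and rose in 3 (9 and 3 adjusted over the list alone, median −0.19, but 0.04 with TPM, adjusted p = 0.0254, estimated 0.233, and 0.0764 after length adjustment). With siTIP60-11 alone neither the hypoxia nor the ribosome biogenesis list was called (adjusted p = 0.0877 for each).

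The replication and cell-cycle lists were not called after TIP60 depletion in SW480. Pre-replication genes had 1 of 14 higher and 4 lower (median 0.04, downward after length adjustment, mean −0.03, camera's direction downward, adjusted p = 0.997). Fork genes had 2 of 37 higher and 3 lower (1 and 2 adjusted over the list alone, median 0.07, adjusted p = 0.457). Other G1/S genes had 4 of 34 higher and 1 lower (median 0.19, adjusted p = 0.0822, ASF1B 0.81 ± 0.0792) and repair genes 1 of 27 higher and 2 lower (median 0.21, adjusted p = 0.155). With siTIP60-2 alone, fork (median 0.23, adjusted p = 0.00461), G1/S (0.43, 5.18e-05) and repair genes (0.40, 0.00306) were called higher, calls lost with an estimated correlation (adjusted p = 0.218, 0.144 and 0.142). With siTIP60-11 their medians were −0.16, −0.04 and −0.05, without a call. G2/M genes had 2 of 35 higher and 10 lower (2 and 11 adjusted over the list alone, median −0.14, but 0.16 with TPM, adjusted p = 0.0517). With siTIP60-11 alone they were called lower (median −0.21, adjusted p = 0.00168, estimated 0.320), with siTIP60-2 not (−0.10, adjusted p = 0.350). They were called lower after length adjustment (0.0101) and without siBRD8-36 replicate 2 (0.0377) or 3 (0.0478), siBRD8-6 replicate 1 (0.0491), 2 (0.0479) or 3 (0.0392), control replicate 2 (0.0424) or 3 (0.0494), siTIP60-11 replicate 1 (0.0358), or siTIP60-2 replicate 1 (0.0450) or 3 (0.0298).

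Further lists without a call in SW480 after TIP60 depletion were the TIP60 complex subunits (3 of 16 higher, 6 lower, median −0.10, but 0.14 with TPM, mean 0.01, adjusted p = 0.685, EPC1 0.75 ± 0.106) and histone genes (2 of 25 higher, 1 lower, median −0.18, adjusted p = 0.623, H2BC5 1.33 ± 0.131). Interferon-stimulated genes had 4 of 32 higher and 4 lower (5 and 5 adjusted over the list alone, median 0.06, adjusted p = 0.457, OAS2 1.56 ± 0.107). NF-kappaB genes had 3 of 11 higher and 1 lower (median 0.18, adjusted p = 0.262, BIRC3 1.66 ± 0.119) and cholesterol genes 2 of 24 higher and 8 lower (median −0.18, but 0.03 with TPM, adjusted p = 0.155, FDPS −0.64 ± 0.0484). Epithelial genes had 4 of 16 higher and 4 lower (6 and 4 adjusted over the list alone, median −0.05, but 0.12 with TPM, mean 0.06, camera's direction upward, adjusted p = 0.997, ESRP1 −1.39 ± 0.0626). Mesenchymal genes had 5 of 16 higher and 3 lower (median 0.16, adjusted p = 0.217, FN1 0.93 ± 0.0576). The 2 fibroblast genes had a median of 0.45, and the 4 leukocyte genes, 3 of them higher, a median of 1.2 (adjusted p = 0.150, CORO1A 1.1 ± 0.129).

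**Figure D2:**
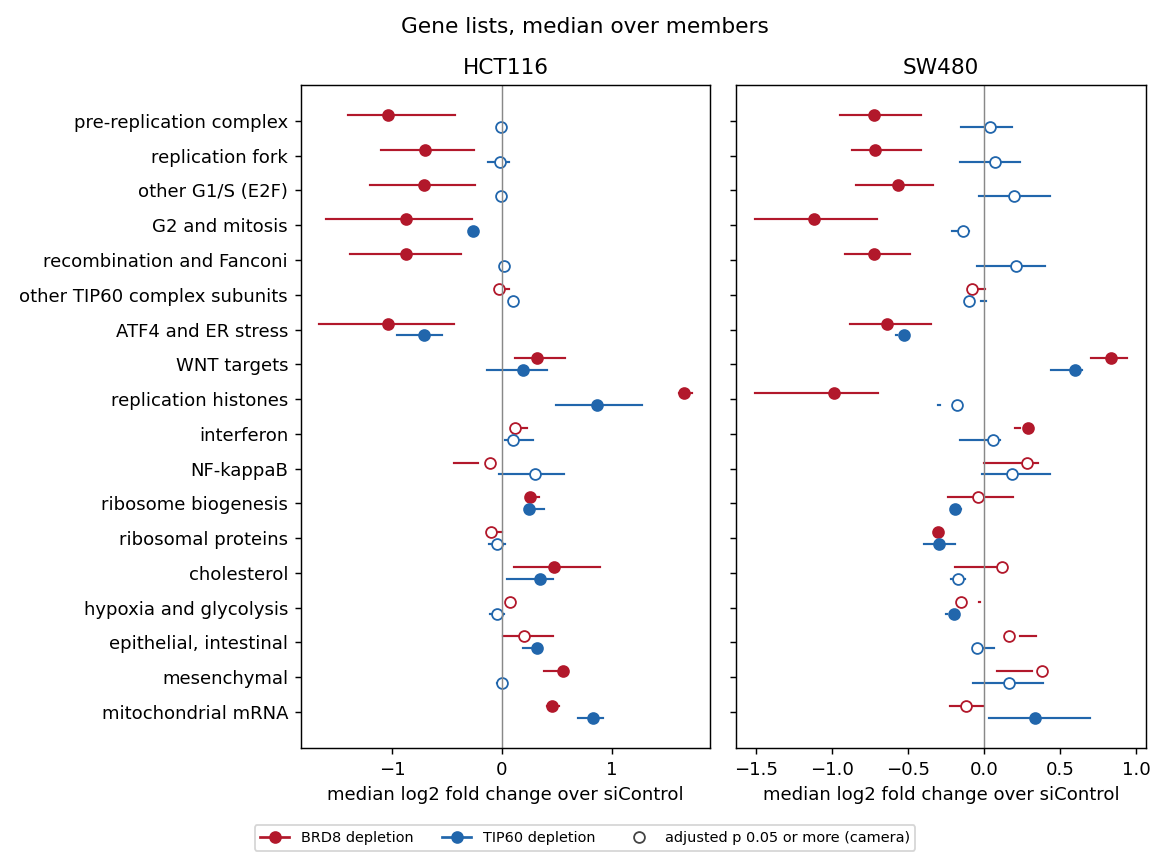
Median log2 fold change of 18 gene lists against control for BRD8 and TIP60 depletion in HCT116 and SW480. Points are the mean of the 2 siRNAs, lines join the medians of the single siRNAs, and open points mark lists with a camera adjusted p of 0.05 or more. The pre-replication list lay at −1.04 and −0.73 after BRD8 depletion and at about −0.00 and 0.04 after TIP60 depletion, the signs of the last values depending on the scaling.

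Whether loss of BRD8 acts like loss of the acetyltransferase of its complex was addressed by testing the difference between both depletions, without reference to the control libraries. Pre-replication genes were lower after BRD8 than after TIP60 depletion in 13 of 14 cases in HCT116 (median difference −0.99, camera adjusted p = 2.16e-09, and 0.00800 with an estimated correlation). They were lower in 13 of 14 in SW480, where 1 was higher (−0.68, adjusted p = 2.33e-07, estimated 0.0183). For 10 of the 14 in HCT116 and 7 in SW480, each BRD8 siRNA lay below each TIP60 siRNA. MCM4 had log2 fold changes of −1.46 and −1.43 with siBRD8-6 and siBRD8-36 in HCT116 and of 0.48 and 0.09 with siTIP60-2 and siTIP60-11, and of −1.0 and −0.61 against 0.59 and 0.07 in SW480.

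**Figure D3:**
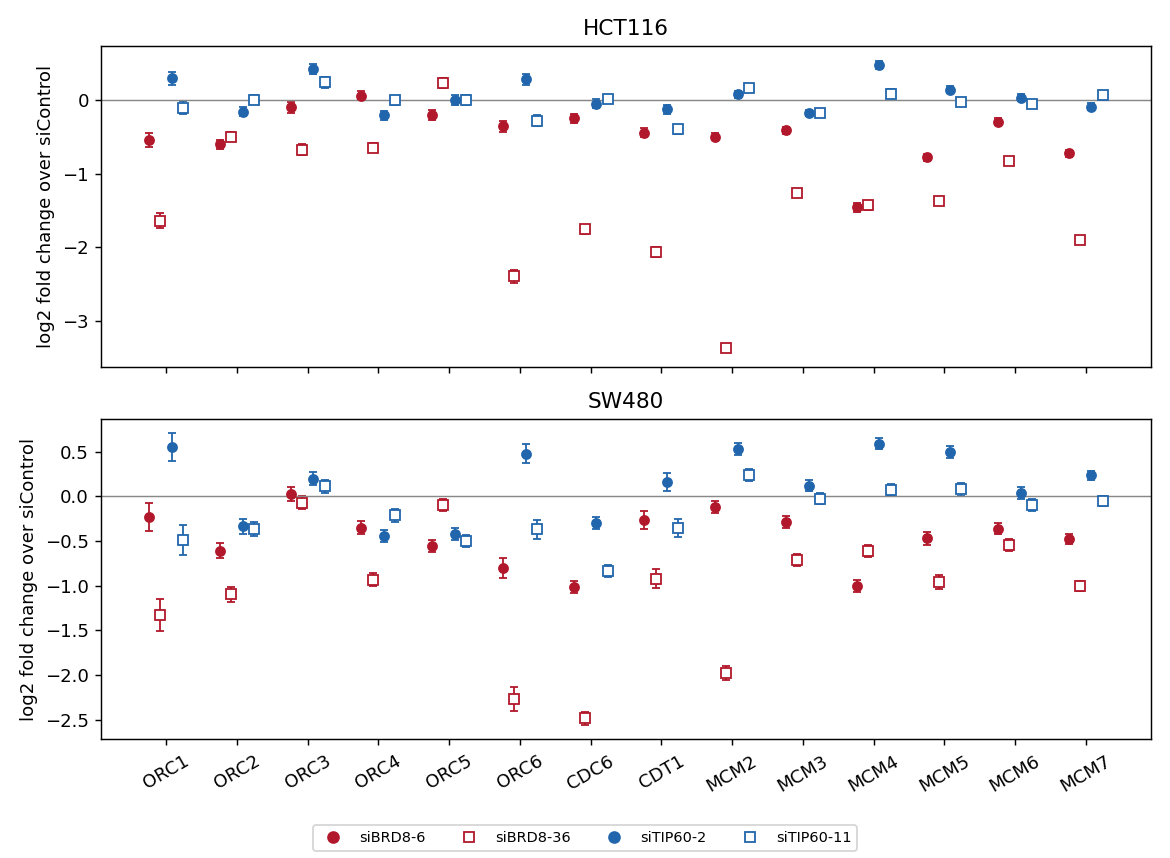
Log2 fold change against control of the 14 pre-replication genes for each siRNA in HCT116 and SW480, with SE. Among the BRD8 siRNAs, siBRD8-36 gave the larger decreases in most members, with list medians of −1.40 in HCT116 and −0.95 in SW480 against −0.43 and −0.41 with siBRD8-6.

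On the mean of both siRNAs, the other proliferation lists also lay lower after BRD8 than after TIP60 depletion, while fewer members had each BRD8 siRNA below each TIP60 siRNA. Fork genes were lower after BRD8 depletion in 36 of 37 cases in HCT116, with 1 higher (median −0.71, adjusted p = 2.76e-13, estimated 0.00193) and in 35 in SW480 (−0.69, 2.94e-14, estimated 0.00723). Other G1/S genes were lower in 29 of 34 with 2 higher (−0.68, 1.06e-12, estimated 0.0239) and 32 of 34 with 2 higher (−0.67, 8.96e-13, estimated 0.0157). G2/M genes were lower in 32 of 35 and higher in 1 in HCT116 (33 and 1 adjusted over the list alone, −0.60, 4.28e-13, but 0.0552 with an estimated correlation) and in all 35 in SW480 (−0.91, 2.73e-21, estimated 0.00333). Repair genes were lower in 25 of 27 and higher in 1 in HCT116 (−0.93, 9.37e-11, but 0.0552 with an estimated correlation) and 23 of 27 in SW480 (−0.80, 6.69e-11, estimated 0.00333). In HCT116, histone genes were higher after BRD8 depletion in 6 of 8 cases (median 0.72, adjusted p = 0.00494, estimated 0.0397), and so were mesenchymal genes in 10 of 16, with 2 lower (0.50, 0.00494, estimated 0.0397). Each BRD8 siRNA lay below each TIP60 siRNA for 11 of 37 fork genes, 10 of 34 other G1/S genes, 6 of 35 G2/M genes and 14 of 27 repair genes in HCT116. In SW480 these counts were 16, 13, 23 and 14. Each lay above for 4 of the 8 histone genes in HCT116 and for 3 of the 16 mesenchymal genes there, with 1 below. In HCT116, the G2/M median was −0.28 with siBRD8-6 and −1.60 with siBRD8-36, against −0.24 with each TIP60 siRNA, so that the difference stood mostly on siBRD8-36.

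Single genes differed as well, each with both BRD8 siRNAs on one side of both TIP60 siRNAs. In HCT116, the tubulin gene TUBA1A rose with the BRD8 siRNAs (1.13 and 1.99) and fell with the TIP60 siRNAs (−1.06 and −0.86, difference 2.53 ± 0.0551, adjusted p = 7.60e-17). UGCG, which makes glucosylceramide, did the reverse (−1.23 and −0.75 against 1.26 and 1.62, −2.43 ± 0.0462, adjusted p = 1.32e-17). KRT13 was lower after BRD8 than after TIP60 depletion (−4.12 ± 0.124), as was IGFBP3 (−2.50 ± 0.122), and TPM1 (2.24 ± 0.0537) was higher. In SW480, GZMB fell after BRD8 and rose after TIP60 depletion (difference −5.02 ± 0.158, adjusted p = 9.82e-19). SNAI2, a repressor of epithelial genes, was lower after BRD8 depletion (−2.13 ± 0.0821), and the apolipoprotein gene APOE (2.13 ± 0.0706) and the phosphatase gene PTP4A3 (2.50 ± 0.106) were higher. The test called 9831 genes in HCT116 (4780 higher and 5051 lower after BRD8 depletion) and 9154 in SW480 (4536 and 4618). Of these, 1946 (1003 and 943) and 1676 (833 and 843) met the four-way condition. Mixed pairs (1 BRD8 and 1 TIP60 siRNA each) differed in up to 8594 and 7694 genes. Most of the calls thus need not come from the target.

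The following differences between BRD8 and TIP60 depletion were called but lost with an estimated correlation. Cholesterol genes were higher after BRD8 depletion in HCT116 (15 of 24 higher, 6 lower, median 0.20, adjusted p = 0.0165, estimated 0.112) and SW480 (13 higher, 3 lower, 0.12, 0.0198, estimated 0.0771). Mitochondrial mRNAs were lower (11 of 13, −0.39, 0.0165, estimated 0.594, and 13 of 13, −0.44, 3.81e-07, estimated 0.209), with the mitochondrial share of counts highest with siTIP60-11 in both lines. In SW480, histone genes were lower (15 of 25, with 2 higher, −0.95, or −0.50 with TPM, 0.0209, estimated 0.313). Ribosome biogenesis genes were higher (16 of 29, with 3 lower, 0.18, 0.0135, estimated 0.0771) and WNT targets higher (13 of 23, with 6 lower, 0.20, 0.0404, estimated 0.260, and 0.0552 without siBRD8-36 replicate 3).

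No difference between the depletions was called for the other lists. In HCT116 these were TIP60 complex subunits (5 of 16 higher, 9 lower, median −0.13, adjusted p = 0.893). They were also interferon-stimulated genes (13 of 32, 7, 0.14, 0.459), NF-kappaB genes (2 of 14, 6, −0.32, 0.239) and WNT targets (6 of 18, 7, −0.01, upward after length adjustment, 0.688). The same held for ribosome biogenesis (9 of 29, 9, −0.08, 0.707), ribosomal proteins (1 of 50, 9, and 5 lower adjusted over the list alone, −0.06, 0.459). No difference was called either for stress genes (12 of 25, 10, and 13 and 10 adjusted over the list alone, median 0.18, mean −0.07, 0.901), hypoxia genes (11 of 23, 4, 0.09, 0.237), epithelial genes (5 of 17, 9, −0.11, 0.245), and leukocyte markers (1 of 4, 2, median −0.24, mean 0.02, 0.901). In SW480 these were TIP60 complex subunits (7 of 16 higher, 8 lower, median −0.06, adjusted p = 0.841). Nor was it called for interferon-stimulated genes (11 of 32, 6, 0.17, 0.20), NF-kappaB genes (4 of 11, 6, −0.20, about 0.00 with TPM, 0.850) or ribosomal proteins (3 of 50, 12, and 3 and 11 adjusted over the list alone, −0.03, upward with TPM or length adjustment, 0.307, and 0.0418 without siBRD8-36 replicate 1). It was not called for stress genes (12 of 26, 12, −0.03, upward with TPM, 0.841), hypoxia genes (10 of 22, 7, median −0.01, upward with TPM, mean 0.07, 0.659). The remaining lists were epithelial genes (9 of 16, 3, and 9 and 4 adjusted over the list alone, 0.17, 0.0787), mesenchymal genes (7 of 16, 6, 0.15, 0.786) and leukocyte markers (1 of 4 higher, 0.04, 0.659). The 2 fibroblast genes had medians of 0.48 in HCT116 and 0.01 in SW480.

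Against control, both depletions also moved many genes the same way. In HCT116, NIBAN1 and ASNS fell and PLK2 and BMP4 rose after either depletion, and in SW480, PROX1 and APCDD1 rose and DDIT3 fell. Called for both targets in one direction were 1632 genes in HCT116 (804 higher, 828 lower), against 542 for independent lists, with 147 in opposite directions, and 1512 in SW480 (682 higher, 830 lower), against 486, with 94 in opposite directions. Across genes, which are not independent replicates, log2 fold changes of the targets correlated with r = 0.558 in HCT116 and 0.565 in SW480. Unchanged groups simulated against the same control libraries gave r = 0.666 ± 0.0315 and 0.697 ± 0.0339 with 0 shared calls by edgeR, and the covariance was 0.210 against a simulated 0.0453 in HCT116 and 0.201 against 0.0476 in SW480. With 3 control libraries a line they cannot be split, and part of the excess may come from the shared controls. A pair of 1 BRD8 and 1 TIP60 siRNA called between 3294 and 3721 genes in HCT116 and between 3034 and 3381 in SW480. Both pairs against a single target called more in each line (3891 and 4436, and 4110 and 3606).

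Across the 13888 genes tested in both, BRD8 depletion moved 1448 genes the same way in HCT116 and SW480 (673 higher, 775 lower, 516 for independent lists, 139 opposite, r = 0.407, rho = 0.462 across genes). TIP60 depletion moved 1473 (704 higher, 769 lower, 516 for independent lists, 106 opposite, r = 0.406, rho = 0.455). The interaction test found 5986 of 17411 genes with a different response to BRD8 depletion (2174 more positive in HCT116, 3812 more negative) and 5423 with a different response to TIP60 depletion (2282 and 3141). The split by direction moved with the scaling and is not fixed by these data. For BRD8 it was 2879 more positive and 3094 more negative with DESeq2 size factors, 3400 and 2924 with length adjustment, 1025 and 4917 with TPM and 3067 and 2378 without SW480 control replicate 3. For TIP60 it was 2709 and 2706 with DESeq2 size factors, 3264 and 2539 with length adjustment and 948 and 4186 with TPM. It was 2762 and 2106 without SW480 control replicate 3 and 2922 and 2327 without SW480 siTIP60-11 replicate 1. The median difference of all genes for BRD8 was −0.10, and −0.20 with TPM. Asking both siRNAs to differ left 2355 and 2286 genes.

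Cholesterol genes responded more positively in HCT116, with 16 of the tested members above and 2 below SW480 for BRD8 depletion (median difference 0.40, camera adjusted p = 1.47e-09, and 5.44e-05 with an estimated correlation). For TIP60 depletion 18 lay above and 1 below (0.41, 1.65e-11, estimated 1.44e-05). Ribosome biogenesis genes did so with 14 and 1 (0.20, 3.81e-06, estimated 0.00559) and 22 above (0.41, 6.93e-15, estimated 1.44e-05). Histone genes did so after BRD8 depletion (10 of 26 above, fitted median 1.86, 3.95e-08, estimated 0.00935). Of these, 7 had a group at 0 counts, and the median with the floor was 2.01. The 8 members tested in both lines had a median of 1.55 (adjusted p = 2.75e-05, estimated 0.00131). The part due to SW480 controls, apart in 7SK and 7SL, was not tested. NF-kappaB genes responded more negatively to BRD8 depletion in HCT116 (8 of 14 below, −0.42, 0.00858, estimated 0.0241). Epithelial genes responded more positively to TIP60 depletion (9 of 18 above, 2 below, 0.22, 0.00177, estimated 0.0487, and 0.31 with the floor). With TPM, the medians for BRD8 depletion were 0.22 (cholesterol), 0.07 (ribosome biogenesis) and 1.07 (histones), or 0.42, 0.27 and 1.27 less the median of all genes. For TIP60 depletion they were 0.20 (cholesterol), 0.19 (ribosome biogenesis) and 0.12 (epithelial genes), or 0.38, 0.37 and 0.30 less the median of all genes.

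KRT13 and KRT80 rose after TIP60 depletion in HCT116 and less or not in SW480 (differences 4.90 ± 0.205, adjusted p = 1.32e-18, and 3.15 ± 0.136, adjusted p = 2.33e-18). PLPPR4 went the other way, with changes of −1.18 in HCT116 and 1.66 in SW480 (difference −2.85 ± 0.237, adjusted p = 2.72e-11). After BRD8 depletion, BCL2L15 (3.50 ± 0.285, adjusted p = 1.15e-11) and LCP1 (2.76 ± 0.425, adjusted p = 3.55e-06) responded more positively in HCT116. The LCP1 change in HCT116 was 1.39 with siBRD8-6 and 5.89 with siBRD8-36. BCL2L15, LCP1 and KRT13 had lowest group means of 6.33, 6.33 and 9.67 counts, and many other large differences lay nearer the floor. The next were picked, after values were seen, among genes averaging at least 10 counts in every group. WNT9A (1.15 in HCT116 and −1.40 in SW480, difference 2.55 ± 0.131) and the linker histone gene H1-2 (2.43 ± 0.151) responded more positively to BRD8 depletion in HCT116.

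The following list differences between lines were called but lost with an estimated correlation. For BRD8 these were pre-replication genes (median −0.39, adjusted p = 0.0483, estimated 0.307), other G1/S genes (−0.21, 0.0410, estimated 0.397), G2/M genes (0.04, downward with TPM, 0.0384, estimated 0.490). So were WNT targets (−0.17, or −0.50 with group counts of at least 3, 0.00858, estimated 0.117), ribosomal proteins (0.18, downward with TPM, 2.71e-05, estimated 0.545). The others were stress genes (−0.35, 0.00352, estimated 0.371), mesenchymal genes (0.11, downward with TPM, 0.0483, estimated 0.226) and mitochondrial mRNAs (0.53, 4.39e-05, estimated 0.307). For TIP60 these were G1/S genes (−0.22, 0.00896, estimated 0.364), G2/M genes (−0.20, 0.0121, estimated 0.415), histones (0.83, 0.00808, estimated 0.303), ribosomal proteins (0.20, 2.55e-06, estimated 0.458), stress genes (−0.44, 0.000852, estimated 0.364) and mitochondrial mRNAs (0.39, 0.000545, estimated 0.364). Their medians moved with the scaling. With TPM and after length adjustment they were −0.62 and −0.23 (pre-replication), −0.38 and −0.04 (G1/S), −0.61 and −0.06 (WNT) and −0.56 and −0.26 (stress) for BRD8, and −0.40 and −0.09 (G1/S) and −0.43 and −0.12 (G2/M) for TIP60. With TPM mitochondrial mRNAs stood at 0.30 (BRD8) and 0.21 (TIP60), and histones at 0.51 and ribosomal proteins at 0.03 for TIP60. Several of these calls ended without 1 library. For BRD8, pre-replication genes were called in 6 of 30 such fits (adjusted p = 0.0389 to 0.111), other G1/S genes in 11 (up to 0.171) and mesenchymal genes in 8 (up to 0.0931). G2/M genes lost their call for BRD8 without HCT116 control replicate 2 (0.248) or SW480 siBRD8-36 replicate 1 (0.0587). For TIP60, G1/S genes lost it without SW480 control replicate 3 (0.0515) or siTIP60-11 replicate 3 (0.0592), and histones without SW480 siTIP60-11 replicate 3 (0.0526). G2/M genes lost it for TIP60 without HCT116 control replicate 3 (0.0931), SW480 control replicate 1 (0.0622), 2 (0.0822) or 3 (0.0774), or SW480 siTIP60-11 replicate 1 (0.0797), 2 (0.0724) or 3 (0.0658). Not called for BRD8 were fork genes (−0.09, upward after length adjustment, adjusted p = 0.459), TIP60 complex subunits (0.08, downward with TPM, 0.230), repair genes (−0.18, 0.230). The same held for interferon-stimulated genes (−0.10, upward after length adjustment, 0.642), hypoxia genes (0.03, downward with TPM, 0.0973), epithelial genes (−0.09, 0.917) and leukocyte markers (−1.70, 0.689). The hypoxia list was called without SW480 control replicate 1 (0.0249), 2 (0.0183) or 3 (0.0173), or SW480 siTIP60-11 replicate 1 (0.0201), 2 (0.0183) or 3 (0.0205). Not called for TIP60 were pre-replication genes (−0.05, upward by camera and after length adjustment, 0.836), fork genes (−0.14, 0.103), TIP60 complex subunits (−0.03, upward after length adjustment, 0.486), repair genes (−0.12, 0.500). Nor were interferon-stimulated genes (−0.07, upward after length adjustment, 0.836), NF-kappaB genes (−0.08, upward after length adjustment, 0.430). The rest were WNT targets (−0.29, or −0.53 with group counts of at least 3, 0.103), hypoxia genes (0.08, downward with TPM, 0.140), mesenchymal genes (−0.37, 0.103) and leukocyte markers (−1.68, 0.836).

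Both siRNAs against a target were set against each other to see how far they acted alike. Genes differed widely between them: ITGB1, the integrin beta-1 subunit, had log2 fold changes of −4.48 with siTIP60-2 and −0.58 with siTIP60-11 in HCT116 (difference −3.90 ± 0.0585, adjusted p = 5.38e-19). The values were −3.82 and 0.17 in SW480 (−3.99 ± 0.0636, adjusted p = 2.24e-26). KCTD3 had 0.35 with siBRD8-6 and −3.75 with siBRD8-36 in HCT116 (4.11 ± 0.0797, adjusted p = 1.39e-17), the semaphorin receptor gene NRP1 −1.97 and 2.09 (−4.06 ± 0.151), and in SW480 the calpain gene CAPN2 −3.64 and −0.06 (−3.59 ± 0.0655). TYMS had 0.24 with siTIP60-2 and −2.33 with siTIP60-11 in SW480 (2.57 ± 0.0843). The siRNAs against BRD8 differed in 9028 genes in HCT116 and 8071 in SW480, and those against TIP60 in 7316 and 6925. Single siRNAs against control called 8040 (siBRD8-6), 9273 (siBRD8-36), 7921 (siTIP60-2) and 8531 (siTIP60-11) genes in HCT116, and 7952, 8679, 7556 and 7266 in SW480. By sites, genes lower with both siRNAs were 14.3% without and 19.1% with sites of both for TIP60 in HCT116, 14.2% and 15.4% for BRD8 in SW480, and 565 of 4035 and 642 of 4704 for TIP60 in SW480.

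Between siRNAs of one target, calls shared with control as reference went in one direction for 4437 genes and in opposite directions for 1294 with BRD8 in HCT116 (r = 0.469 across genes). The counts were 4882 and 667 with TIP60 in HCT116 (r = 0.598), 4621 and 870 with BRD8 in SW480 (r = 0.510) and 4130 and 542 with TIP60 in SW480 (r = 0.555). These pairs share control libraries, and unchanged groups simulated with shared controls gave r between 0.506 and 0.530. Across lines, where no libraries are shared, and over 10648 genes, the same siRNA gave a mean r of 0.553 (0.489 to 0.626), the other siRNA of the same target 0.254 (0.219 to 0.332) and an siRNA of the other target 0.164 (0.0566 to 0.227).

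**Figure D4:**
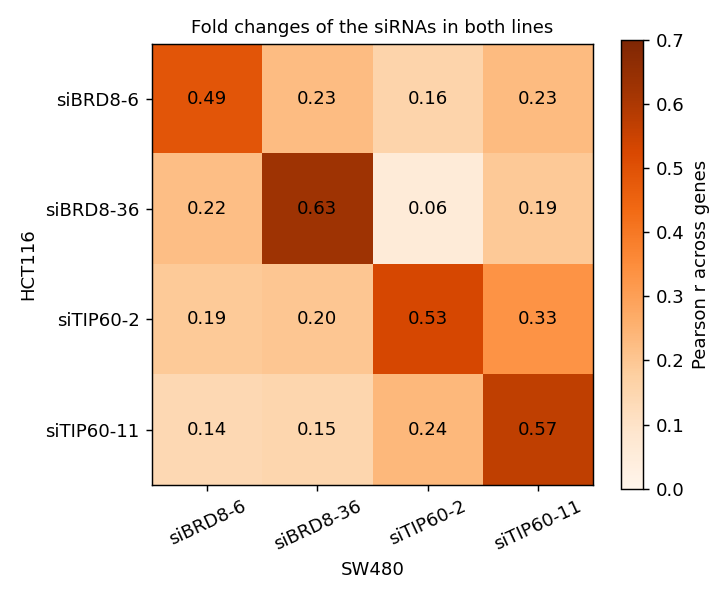
Pearson r across 10648 genes between the log2 fold changes of each siRNA in HCT116 and each siRNA in SW480. The same siRNA lies between 0.489 and 0.626, the other siRNA of the same target between 0.219 and 0.332, and the other target between 0.0566 and 0.227.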

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

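The results below were picked by a filter chosen after the values had been seen: each is a tested difference in response between HCT116 and SW480 whose call stood with an estimated correlation (lists reported here), or a gene named by the rule with a mean count of at least 3 in every group. The tests of lists with group counts set to a floor, with shared genes alone and without single libraries were also chosen only after the results were seen.

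Responses differed between the lines for 5986 genes after BRD8 depletion and for 5423 after TIP60 depletion. Random splits within each line reached these counts in 1 of 40 cases, the real one (highest others 2747 and 2055), which argues against random grouping. Each difference also holds any shift shared by the SW480 control libraries, which stood apart, and this was not tested. Differences of list medians, HCT116 minus SW480, were 1.86 (histones), −0.42 (NF-kappaB), 0.20 (ribosome biogenesis) and 0.40 (cholesterol) after BRD8 depletion. They were 0.41 (ribosome biogenesis), 0.41 (cholesterol) and 0.22 (epithelial) after TIP60 depletion. With TPM, which shifted the median of all genes by −0.20 (BRD8) and −0.18 (TIP60), they were 1.07, −0.48, 0.07 and 0.22, and 0.19, 0.20 and 0.12, that shift included. The 30 fits without 1 library, run only at the preset correlation, called all 7 differences. The histone median stands partly on members at 0 in HCT116 (2.01 with the floor). Among genes, BCL2L15 (3.50) and LCP1 (2.76) differed between lines after BRD8 depletion, and KRT13 (4.90), KRT80 (3.15) and PLPPR4 (−2.85) after TIP60 depletion.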

How the results depend on the processing

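The tests with four-way calls, with both siRNAs between lines, with adjustment for gene length and with shared genes were chosen only after the results were seen. Of 433 named-gene results, 327 kept direction and side of the threshold in every alternative, and the genes described in the text were drawn mostly from those, a choice made after the values were seen. Of the 433, 417 kept direction and side with DESeq2 (15 weaker, 1 stronger), 432 with its size factors, 421 without a filter, 431 with a stricter filter, 409 with length adjustment (20 weaker, 2 stronger, 2 reversed) and 347 with limma on log2(TPM + 1) (78 weaker, 2 stronger, 6 reversed). Of 4209 fits of a named gene without 1 library, 4036 kept both, 164 were weaker, 3 stronger and 6 reversed. The cause of these changes was not tested.

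Reversed with TPM were ACTL6A (0.0446), MT-CO1 (0.0231) and MT-ND1 (0.0246) after BRD8 and ORC2 (0.0397) after TIP60 depletion in SW480, and LBH (−0.85) and OVOL1 (0.21) between lines. Reversed with length adjustment after BRD8 depletion in SW480 were COL1A1 (−0.0678) and TRRAP (−0.0130). Without single libraries, COL1A1 in BRD8 SW480 comparisons, which was not called, lay between −0.0503 (without control replicate 3) and 0.0646 (without control replicate 1), against 0.0051 with all libraries. It was also negative without siBRD8-36 replicate 1 (−0.03) or 2 (−0.02) and siBRD8-6 replicate 1 (−0.01) or 3 (−0.01). After TIP60 depletion it lay between −0.11 (without control replicate 3) and 0.00173 (without control replicate 1), against −0.06 with all libraries.

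At least 2-fold changes with both siRNAs left 358 (BRD8) and 435 (TIP60) genes in HCT116 and 436 and 285 in SW480, 1044 and 1038 between targets, 1102 (BRD8) and 828 (TIP60) between lines, and 1913 and 1682 (BRD8) and 996 and 909 (TIP60) between siRNAs in HCT116 and SW480. The mean of both siRNAs called 8766 (BRD8) and 8529 (TIP60) genes in HCT116 and 8518 and 7717 in SW480. limma on log2(TPM + 1) called 2375 and 2764 in HCT116. Four-way calls numbered 1946 and 1676, and calls with both siRNAs between lines 2355 and 2286. With fry, 17 lists were called for BRD8 in SW480, 14 for TIP60 in HCT116 and 17 for TIP60 in SW480, and with an estimated correlation 1 for TIP60 in HCT116 and 2 in SW480.

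Across genes, r between targets in HCT116 (0.558) was 0.626 with DESeq2, 0.517 at a mean count of at least 50, 0.526 with limma, 0.631 without a filter, and 0.399, 0.429, 0.446 and 0.452 for single pairs of siRNAs. In SW480 (0.565) these were 0.650, 0.512, 0.527, 0.671, and 0.371, 0.413, 0.488 and 0.468. Between lines r was 0.542 at a mean count of at least 50, 0.489 with siBRD8-36 and 0.356 with siBRD8-6 for BRD8 (0.407), and 0.529, 0.441 with siTIP60-11 and 0.382 with siTIP60-2 for TIP60 (0.406).

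Without 1 library, counts ranged from 3389 to 4080 for BRD8 and from 3897 to 4603 for TIP60 in HCT116, and from 3435 to 3980 and 2990 to 3454 in SW480. Between targets they ranged from 9426 to 9615 and 8762 to 9179, between lines from 5250 to 6352 and 4682 to 5907, and between siRNAs from 8297 to 8592 and 7345 to 7992 (BRD8) and 6373 to 6612 and 6014 to 6576 (TIP60). Lists called numbered 12 to 14, 10 to 11, 9 to 9 and 6 to 7 for BRD8 in HCT116 and SW480 and TIP60 in HCT116 and SW480. The r between targets lay between 0.555 and 0.639 in HCT116 and 0.549 and 0.638 in SW480, and r between lines between 0.353 and 0.410 for BRD8 and 0.331 and 0.405 for TIP60.

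Replicates share only a number and were not paired by the labels. Taking the replicate number as a block gave 4069 genes for BRD8 in HCT116 against 3891 and changed the call of 5 named genes. In HCT116, 13 of 15 libraries correlated best with a library of their own number (mean r 0.0666), and in SW480 2 of 15 (mean r −0.0174).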

Other observations

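The tests of a state of the SW480 control cultures, of an effect of the control siRNA and of a smaller share of cycling cells were chosen only after the results were seen.

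In both lines, BRD8 and TIP60 depletion moved a common set of genes: 383 genes were called for both targets in one direction in HCT116 and SW480, against 81.9 for independent lists, with 9 in opposite directions. In SW480 alone, 1512 genes were shared, and 1442 were counted after the trend with gene length was taken out and 1401 after all libraries were thinned to 7069580 counts, which argues against either as the whole cause. The 383 genes, found against separate control libraries, also argue against a state of the SW480 control cultures alone. An effect of the control siRNA itself cannot be told apart from a common response to both depletions, since the series holds no second control group. For ribosomal protein genes in SW480 the length trend could account for part of the decrease, since their medians went from −0.31 to −0.0695 (BRD8) and from −0.30 to −0.12 (TIP60) with it taken out, and this stays open.

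Each siRNA had its own signature in both lines: for 4 of 4 siRNAs, the 7-mer whose 3' UTR sites went with the lowest changes in HCT116 ranked within the 10 lowest of SW480, and it occurred in a transcript of the target for 4 of 4, where 32.7% of 7-mers occur in transcripts of BRD8 and 19.0% in those of KAT5. A candidate explanation is therefore that seed matches of each siRNA lower other mRNAs, though the siRNA sequences are not in the sources used. Relative to the other siRNAs, genes with a site differed from those without by a mean of −0.42 to −0.18 in HCT116 and −0.41 to −0.17 in SW480, averages that leave open which single genes such sites lower. A deeper knockdown as the whole cause would let the difference between siRNAs in HCT116 (siBRD8-6 minus siBRD8-36, siTIP60-2 minus siTIP60-11) follow the target's mean effect in SW480 about as closely as the same difference there. The r was −0.211 for BRD8 (0.653 with the same difference), with the sign that a deeper knockdown by siBRD8-36 would give, and −0.0225 for TIP60 (0.622), sizes that argue against depth as the whole cause and leave a part open for BRD8.

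Pre-replication genes were lower after BRD8 than after TIP60 depletion in both lines. With the length trend taken out, their median after BRD8 depletion was −1.02 in HCT116 and −0.74 in SW480, and the 5 of 14 members without a BRD8 siRNA site had medians of −1.08 and −0.72, which argues against length and seed sites as the whole cause. Other pairings of the 4 siRNAs gave at most 763 four-way genes against 1946 in HCT116 and 555 against 1676 in SW480, and 0 pre-replication genes by edgeR against 10 and 7. The decrease may belong to a smaller share of cycling cells, as the 3 other cell-cycle lists fell too: pre-replication genes fell further in HCT116 (permutation p = 0.0138, −1.04 against −0.73) but not detectably in SW480 (p = 0.763, −0.73 against −0.78), which leaves it open.

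Of 100 splits of the libraries, the real one included, 3 called at least as many genes as it for BRD8 in HCT116 (3891, highest other 5434) and 2 in SW480 (4110, highest other 4240). For TIP60 only the real split did, in HCT116 (4436, highest other 2947) and SW480 (3606, 2188). These splits mix siRNAs and exclude chance for neither target. The cause of the higher splits for BRD8 was not tested. For the number of lists called, chance cannot be excluded: 22 of 100 gave as many for BRD8 in HCT116 (13, highest other 15) and 37 in SW480 (10, 14). For TIP60 it was 10 (9, 12) and 42 (6, 10). For the difference between targets, only the real split of 100 reached 9831 in HCT116 (highest other 1241) and 9154 in SW480 (1494). Those splits mix siRNAs, and whole siRNAs allow too few pairings to exclude chance. Comparisons of 3 against 3 libraries allow 10 splits, too few for a share under 0.05. For single siRNAs and between siRNAs the real counts lay between 6925 and 9273, with at most 1 gene called by edgeR in any other split.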
